A study of Danio rerio with 16 samples.

How the data were processed

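Gene expression was measured in zebrafish larvae exposed for 96 h to IMX-101 that had first been irradiated with ultraviolet (UV) light. IMX-101 is an insensitive explosive formulation made of dinitroanisole, nitrotriazolone and nitroguanidine. Per the labels' protocols, stock solutions were irradiated for 4 h in a photo-reactor, each beaker held 10 larvae, the solution was not renewed, and RNA was extracted from 4 whole fish of each beaker. Besides the control (0), larvae were kept at 58.2, 30.2 or 3.8 mg/L, concentrations measured before the irradiation, per the labels. The series text lists another value in place of the 58.2 mg/L of the sample labels, and the sample labels were used. Dead fish were removed daily, per the labels' protocols, so the RNA came from survivors. Each group had 4 beakers and 4 arrays, 16 in all, and no arrays were pooled. Survival data, the untreated material and the other compound of the same study were not analysed here.

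Each sample was hybridised to a 1-colour Agilent array (design 036575) labelled with Cy3. The scanner values are intensities extracted with Agilent Feature Extraction 10.7.3.1, per the file headers. Per the file headers, the processed intensity had been background-subtracted and detrended and was replaced by a surrogate value near background. Nothing in the headers scales one array to another. The deposited value table was in log2 units, and how it was made is not given in the sources used here. Set against the scanner values, each of its columns followed log2 of the processed intensity shifted to the array's 75th percentile and centred on each probe's median over the 16 arrays, with r of 0.994 to 0.999 and slopes of 0.994 to 1.003 across probes. Its column medians ran from -0.30 to 0.21, and it was used only as an alternative source of values. Its direction followed the scanner values, and its absolute level was lost by the centring.

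The arrays held 62976 spots, of which 61657 were not controls, for 43603 probes, and no spot was saturated. The arrays lay on 4 slides. Slide 1 held replicate 1 of all 4 groups. Slide 2 held control replicates 2 and 3 and replicate 2 of each exposed group. Slide 3 held control replicate 4, replicate 3 of each exposed group and 58.2 mg/L replicate 4. Slide 4 held replicate 4 of the 3.8 and 30.2 mg/L groups and no control. The files recorded 5 scans, which followed the slides except that 3.8 mg/L replicate 2 was scanned apart. The number of arrays limits the precision of the values.

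The main values were log2 of the processed intensity minus each array's 75th percentile. Spots marked as non-uniform or population outliers by the extraction software were left out, replicate spots of a probe were averaged, and control spots were removed. A probe was kept when it was well above background on at least 4 of the 16 arrays and had a value on at least 12, which kept 36224. Probes were named through the given tables (assembly GRCz12tu, used for names only): 27731 by accession and 5226 by symbol or synonym. Another 4068 kept the name in the file and 6578 stayed unnamed. The 399 probes whose accessions matched several symbols were not named by accession and are counted within the other classes. Of the 8796 genes with several kept probes, the probe with the brightest mean was used. The result was 22046 features, of which 17801 were named, 14046 of these with a current symbol, and 4245 were unnamed probes. Features are called genes in the results. Probes of near-identical paralogs, such as the hsp70, globin and opsin genes, may share signal, and this was not resolved. Probe positions are those of the array's design on Zv9 (danRer7).

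Groups were compared with limma (lmFit and eBayes) in 1 fit of all 16 arrays with no covariate, with Benjamini-Hochberg adjustment at 0.05. The 3 exposed groups were each compared with the control, the 58.2 mg/L group with each lower concentration, and a moderated F test asked for any difference from the control. Gene lists, 32 in all (21 pathways and 11 tissues or cell types), were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry. All p-values of genes and lists given as adjusted come from limma. The comparisons, tests, lists and the alternatives listed below were fixed before the data were examined. Genes were named by a rule fixed at the same time. It took the 12 largest rises and 12 largest falls among genes with a symbol past the threshold whose 4 exposed arrays all lay on one side of the 4 controls. It added, for each list, up to 4 members past the threshold by p, or up to 2 members given as values where none passed. Where fewer than 5 genes passed, it gave 10 genes by p as values. A gene not well above background on any array of a group has only a bound there. Its fold is given as "at least", from the brighter group's mean against, per array, the higher of the dim probe's own value and the lowest signal among probes well above background. Such a bound holds for the main values, and the alternatives can give smaller changes.

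The alternatives were normexp background correction (offset 50) with quantile normalization, quantile normalization alone, median centring, the deposited value table, and no filter or a filter over all 16 arrays. Further alternatives were the mean of a gene's probes, each probe tested by itself, slide as a fixed or random block, the replicate number as a block, a fit of only the groups compared, a trended and robust variance, array weights, and each array left out in turn. Chosen after seeing the data were a fit without the 2 arrays with the most variable replicate spots, and a loess correction (span 0.3) of each array on probe brightness and GC content. All value columns in the deposited table were assigned to a sample.

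The procedure was tested on 10 simulated data sets for the 58.2 mg/L comparison, with 200 of 21817 genes changed. It recovered 11.6% of genes changed by 1 on the log2 scale, 51.4% at 1.5, 73.0% at 2 and 89.4% at 3. Of all calls in that comparison 9.51% fell on unchanged genes. In the 2 unchanged comparisons 337 calls arose, all in 1 of the data sets. A shifted list was found in 10 of 10 sets and an unshifted one in 0 of 10, at the preset correlation. These lists were 40 genes drawn at random. Members of the real lists vary together, with an estimated correlation of up to 0.72, so false calls of such lists were not tested. R 4.3.3, limma 3.58.1, data.table (version 1.17.8), Python 3.11.15 and matplotlib 3.10.9 were used.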

Results

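Whole zebrafish larvae were sampled after 96 h in water with UV-treated IMX-101, an explosive formulation that sunlight can alter once it is in water. The series was set up to ask what irradiated munition material does to larvae and whether oxidative stress is part of its toxicity. The control group and the groups at 58.2, 30.2 and 3.8 mg/L had 4 arrays each, every array carrying RNA from 4 fish of a separate beaker. The 75th percentile of the processed intensity ran from 423.1 to 1786 over the arrays, and 65.2% to 82.5% of probes were well above background. Replicate arrays correlated across genes with r of 0.932 to 0.968 in the control, 0.902 to 0.980 at 3.8 mg/L, 0.933 to 0.981 at 30.2 mg/L and 0.952 to 0.980 at 58.2 mg/L, and no pair held identical values. Replicate spots varied most on 3.8 mg/L replicate 2 (coefficient of variation 49.4%) and control replicate 2 (39.2%), against 13.7% on the quietest array. Changes below are log2 differences from the control with their standard error, from limma with n = 4 arrays per group unless stated otherwise.

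At 3.8 mg/L no gene passed the threshold in limma, and the values nearest to it belonged to long-wavelength cone opsins. The red cone opsin genes opn1lw1 and opn1lw2 had changes of 2.36 ± 0.41 (adjusted p = 0.22) and 2.16 ± 0.44 (adjusted p = 0.48), and the green opsin opn1mw3 had 1.06 ± 0.23. The haem oxygenase genes hmox1a and hmox1b, whose products break down haem, had 2.07 ± 0.70 and 1.64 ± 0.42, both short of the threshold. Lower values were those of csrnp1b (-1.19 ± 0.28), the mitochondrial folate carrier slc25a32b (-1.40 ± 0.32) and ubap1lb (-1.53 ± 0.36). The remaining genes given by the naming rule were vipr1b (1.49 ± 0.34), unk (1.13 ± 0.27), gipc3 and abcc9. The last pair were not well above background on any control array and were at least 1.64-fold and 2.29-fold higher, with adjusted p of 0.53 for each. In vipr1b the value of control replicate 2 stood apart from the other controls.

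No member of any of the 32 lists passed at 3.8 mg/L, and 7 lists were shifted by camera with the preset correlation. Cell cycle genes had a median change of -0.87 (adjusted p = 9.4e-13, but adjusted p = 0.995 with an estimated correlation). Over the arrays this list's median ran from -0.98 to 0.94 in the control and from -2.22 to 0.36 at 3.8 mg/L. Immediate-early genes, which respond within minutes to stimulation, had a median of -0.51 (adjusted p = 1.4e-10, and adjusted p = 0.527 with an estimated correlation), and 3 of 36 were lower when adjusted over the list alone. Endoplasmic reticulum stress genes had a median of -0.18 (adjusted p = 0.00177, and adjusted p = 0.0812 with an estimated correlation), and -0.11 after quantile normalization. Photoreceptor genes (0.39, adjusted p = 6.1e-06), exocrine pancreas genes (0.50, adjusted p = 0.00177), cartilage and bone genes (0.33, adjusted p = 0.0246) and erythroid genes (0.34, adjusted p = 0.0246) had medians above 0. Each of these 4 lists had adjusted p = 0.995 with an estimated correlation. Their within-slide medians were above 0 on slides 1 and 2 but turned on slide 3, to -0.31, -0.45, -0.40 and -0.46 in the same order. Adjusted over the list alone, 3 photoreceptor genes, 2 clock genes, 1 oxidative stress gene and 1 gluconeogenesis gene were higher. In limma 0 of 22046 genes passed, 1349 had an unadjusted p under 0.05, array weights gave 59, and leaving out the 2 arrays with variable spots gave 2. The 7 shifted lists became 13 without control replicate 4, 12 without 3.8 mg/L replicate 3, 14 without 3.8 mg/L replicate 4 and 14 with slide as a block.

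**Figure D1:**
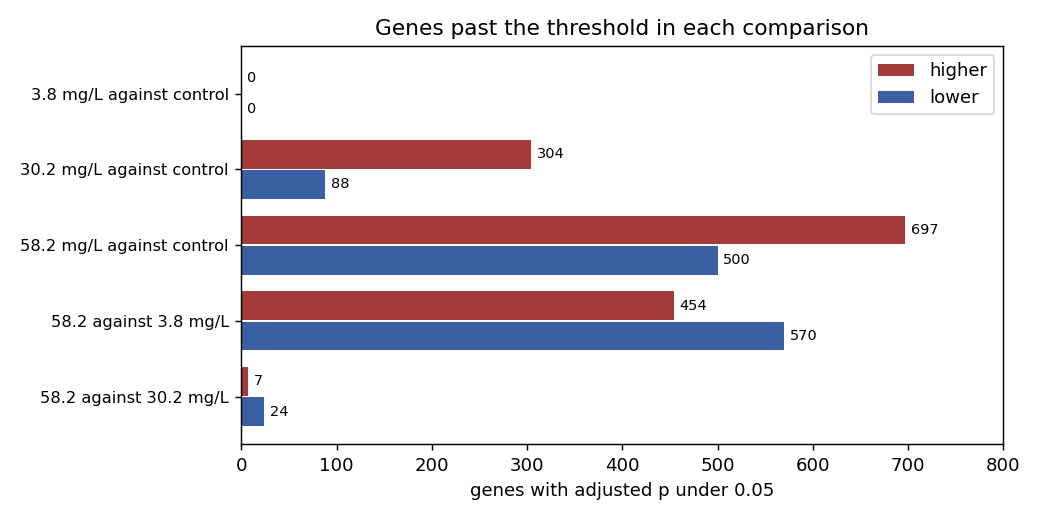
Number of genes with an adjusted p under 0.05 in each comparison, as bars from 0 on a linear axis, with genes higher and lower in the first-named group drawn separately. No bar stands for 3.8 mg/L against control, 304 genes rose and 88 fell at 30.2 mg/L, and 697 rose and 500 fell at 58.2 mg/L.

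At 30.2 mg/L, the largest rises over the control included those of single heat shock, haemoglobin and sterol synthesis genes. Among them was ptgr1.2, a prostaglandin reductase gene, which was not well above background on any control array and was at least 16.7-fold higher (adjusted p = 0.00382). Its fitted change ran from 2.29 to 5.45 over the alternatives, against 3.98 to 4.94 for hsp70.3, so its rank is uncertain. The heat shock genes hsp70.3 (4.49 ± 0.49, adjusted p = 0.000642), hsp70l (3.24 ± 0.46) and hspa1b (3.13 ± 0.62, above background on 1 of 4 control arrays) rose. So did the adult haemoglobin genes hbba2 (4.41 ± 0.84, above background on 3 of 4 control arrays) and hbaa2 (4.03 ± 0.74). The sterol synthesis genes cyp51 (3.66 ± 0.63) and sqlea (3.05 ± 0.43), the glutathione transferase gene gsta.2 (3.56 ± 0.68), hmox1a (3.54 ± 0.70, above background on 3 of 4 control arrays), the muscle ankyrin repeat gene ankrd1b (3.75 ± 0.56) and the anion exchanger gene of red cells slc4a1a (2.97 ± 0.41) completed the largest rises. Normalized hmox1a signal was -3.82 ± 0.99 (SD, n = 4) in the control and -0.28 ± 0.91 (SD, n = 4) at 30.2 mg/L.

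Among the largest falls at 30.2 mg/L was that of itln2, an intelectin gene, not well above background on any exposed array and at least 9.07-fold lower (adjusted p = 0.0180). Its fitted change ran from -4.31 to -1.46 over the alternatives, against -3.65 to -2.88 for krt1-19e, so its rank is uncertain. The keratin gene krt1-19e fell by 3.21 ± 0.47 (adjusted p = 0.00609). The transglutaminase gene tgm5l (-3.02 ± 0.45), the nuclear receptor gene nr0b2a (-2.60 ± 0.39), glipr2l (-2.57 ± 0.58), the glycogen-targeting phosphatase subunit ppp1r3b (-2.44 ± 0.58) and the peptidase gene nln (-2.12 ± 0.37) fell. The histone genes hist1h2a3 (-2.32 ± 0.55) and hist2h3c (-2.03 ± 0.47) also fell, with control replicate 2 lower in hist1h2a3 than the other controls. The odorant receptor gene or30bv1 (-2.77 ± 0.65) was above background on 3 control arrays and 1 exposed array. The gene tmem208 fell by 2.1 ± 0.46 on its brightest probe while its other probe had 0.21, and otud4 fell by 2.07 ± 0.35 with 1 missing array in each group.

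Among the lists at 30.2 mg/L, lipid and sterol synthesis genes rose in 9 of 39 members and fell in 0, with 14 higher when adjusted over the list alone. The list's median was 0.66 (adjusted p = 5.6e-07, and adjusted p = 0.268 with an estimated correlation), and sc5d (2.43 ± 0.38), msmo1 (2.39 ± 0.36) and idi1 (1.65 ± 0.25) were examples. By fry the lipid synthesis list had adjusted p = 0.00215. Of 32 erythroid genes 7 rose, 15 adjusted over the list alone, including alas2 (1.93 ± 0.33), which makes the first enzyme of haem synthesis in red cells. That list had a median of 0.80 (adjusted p = 1.8e-07, and adjusted p = 0.268 with an estimated correlation), with 1.25, 1.05 and 0.58 within the 3 slides that held both groups. Of 32 heat shock genes 5 rose, 9 adjusted over the list alone, among them hsp90aa1.1 (1.99 ± 0.33) and hspb8 (1.62 ± 0.33), with an adjusted p of 0.000399 (adjusted p = 0.268 with an estimated correlation). Proteasome genes rose in 4 of 46 members and in 28 adjusted over the list alone, such as psmb3 (1.33 ± 0.28) and psmd4b (1.23 ± 0.24), together with psma4 and psmb5. Their median was 0.80 (adjusted p = 4.8e-11, and adjusted p = 0.518 with an estimated correlation). By fry the proteasome list had adjusted p = 0.0162. Of 38 oxidative stress (nrf2 target) genes 5 rose, 9 adjusted over the list alone, including gsr (1.51 ± 0.28), pgd (1.37 ± 0.26) and blvrb (1.06 ± 0.21). The median was 0.40 (adjusted p = 0.00589, and adjusted p = 0.757 with an estimated correlation). By fry the oxidative stress list had adjusted p = 0.0440.

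The photoreceptor genes opn1mw3 (1.1 ± 0.23), opn1lw1 (1.76 ± 0.41) and opn1lw2 (1.81 ± 0.44) rose at 30.2 mg/L, 3 of 66 measured, with 5 higher and 1 lower adjusted over the list alone. These calls were lost in 11, 14 and 21 of the 31 alternatives, with adjusted p of up to 0.0987, 0.138 and 0.154. The photoreceptor list had a median of 0.38 (adjusted p = 0.00332), neural genes 0.36 (adjusted p = 0.00638) and neurotransmitter signalling genes 0.54 (adjusted p = 0.000109), each with adjusted p = 0.855 with an estimated correlation. Cell cycle genes had the lowest median, -1.61 (adjusted p = 3.4e-18, and adjusted p = 0.462 with an estimated correlation), with 0 of 48 past the threshold and 33 lower adjusted over the list alone. Within slides that median was -2.54, -1.09 and -1.49. Epidermal genes had a median of -0.56 (adjusted p = 2.5e-07, and adjusted p = 0.671 with an estimated correlation), with krt1-19e alone past the threshold among 46, and -0.36 after normexp and quantile normalization. Ribosomal protein genes (-0.25, adjusted p = 0.000296) and oxidative phosphorylation genes (-0.20, adjusted p = 0.00332) were shifted down, both with adjusted p = 0.855 with an estimated correlation, and their medians turned to 0.07 and 0.01 after normexp and quantile normalization. Outside the shifted lists the aryl hydrocarbon receptor target cyp1a (2.37 ± 0.36), gsto1 (1.53 ± 0.25), cyp2k6 (2.00 ± 0.44), the liver genes fah (1.6 ± 0.28), cyp8b1.1 (1.74 ± 0.35) and tdo2b (1.18 ± 0.27), the iron exporter slc40a1 (1.45 ± 0.36) and the muscle gene desma (1.14 ± 0.23) rose. So did oat (1.68 ± 0.36), nfil3 (1.49 ± 0.31), gpt (1.14 ± 0.25) and matn3a (1.78 ± 0.42), and phospho1 fell by 1.62 ± 0.32. The signal of ptf1a was at least 2.12-fold higher. Within the oxidative phosphorylation list, which was shifted down, ndufa12 alone passed and went the other way, at least 1.71-fold higher. Over the alternatives the fitted changes of ptf1a and ndufa12 ran from 0.43 to 1.69 and from 0.34 to 1.45, so these bounds do not hold under each of them.

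In all 304 genes rose and 88 fell at 30.2 mg/L, with 4802 at an unadjusted p under 0.05. With median centring 222 rose and 97 fell, and with the loess correction 65.7% of calls were rises against 77.6%. On the 3 slides with both groups, 391 of the 391 called genes with a value on each had 1 sign throughout, a share that the choice of genes on the same arrays favours. The count of 392 became 99 without control replicate 1, 793 without control replicate 2, 126 without control replicate 3, 683 without control replicate 4, 138, 98, 62 and 229 without 30.2 mg/L replicates 1 to 4 and 255 without 58.2 mg/L replicate 4. It was 114 with slide as a block and 1147 without the 2 arrays with variable spots, and ptgr1.2, hsp70.3, hsp70l, ankrd1b, cyp51, sqlea, slc4a1a, krt1-19e, nr0b2a and tgm5l passed under each alternative run. With slide as a fixed block, 27 of the 55 genes named at 30.2 mg/L no longer passed, though none changed direction. They were hspa1b, 7 of the 12 largest falls (itln2, or30bv1, ppp1r3b, hist1h2a3, nln, tmem208 and hist2h3c) and 19 of 31 further list members. The latter were gsr, pgd, cyp2k6, hspb8, gpt, psmd4b, psmb3, psma4, psmb5, ndufa12, slc40a1, tdo2b, ptf1a, desma, the 3 opsin genes, phospho1 and matn3a. Of the genes named, calls lost in most alternatives were those of hist1h2a3 (21), slc40a1 (20), psmb5 (19), ppp1r3b (18) and matn3a (18) of up to 31, besides opn1lw2, or30bv1 (16) and ndufa12 (16).

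**Figure D2:**
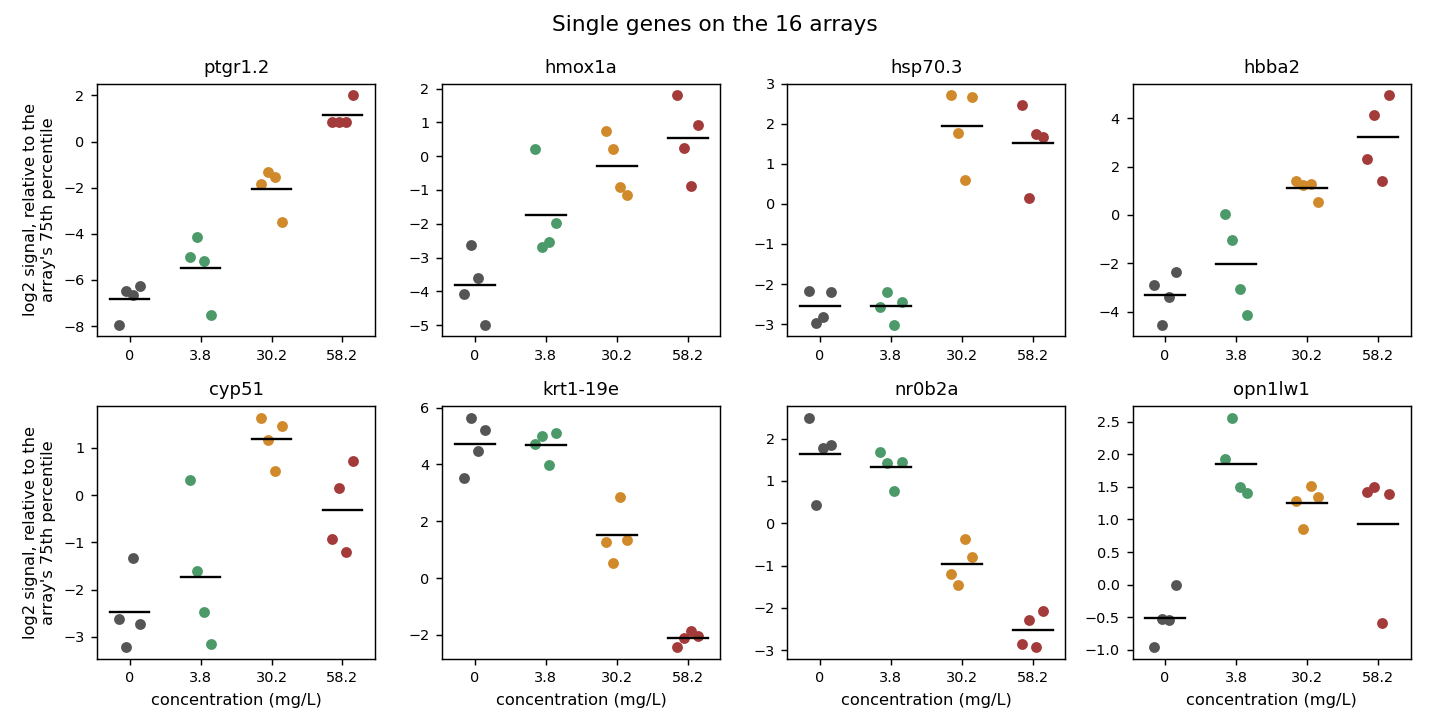
Normalized log2 signal of 8 genes on each of the 16 arrays (dots), by concentration in mg/L, with black lines for group means and an axis of its own for each gene. In krt1-19e the mean goes from 4.71 in the control to 1.5 at 30.2 mg/L and -2.12 at 58.2 mg/L, while hmox1a goes from -3.82 to -0.28 and 0.53.

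At 58.2 mg/L haemoglobin and heat shock genes stood among the largest rises, and the keratin gene krt1-19e had the largest fall. Prostaglandin reductase ptgr1.2 was at least 153-fold higher (adjusted p = 1.1e-05), with 58.2 mg/L replicate 4 above the other exposed arrays. Its fitted change ran from 5.11 to 8.25 over the alternatives, so this bound does not hold under each of them. Haemoglobin genes hbba2 (6.49 ± 0.84, adjusted p = 0.000484, above background on 3 of 4 control arrays) and hbaa2 (6.30 ± 0.74, adjusted p = 0.000263) rose, with slc4a1a (4.26 ± 0.41, adjusted p = 5.8e-05) and alas2 (3.56 ± 0.33, adjusted p = 5.0e-05). The heat shock genes hspa1b (5.42 ± 0.62, above background on 1 of 4 control arrays, so its size is uncertain), hsp70.3 (4.06 ± 0.49) and hsp70l (3.34 ± 0.46), the glutathione transferase gene gsta.2 (5.36 ± 0.68), ankrd1b (4.70 ± 0.56), hmox1a (4.34 ± 0.70, adjusted p = 0.00223, above background on 3 of 4 control arrays) and the small GTPase gene arf4b (4.10 ± 0.52) rose too. The gene krt1-19e fell by 6.83 ± 0.47 (adjusted p = 3.3e-06), from 4.71 ± 0.92 (SD, n = 4) to -2.12 ± 0.23 (SD, n = 4).

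Other large falls at 58.2 mg/L were those of single genes. The inducible nitric oxide synthase gene nos2a fell by 4.79 ± 0.75 and was above background on 1 exposed array. The T cell co-receptor gene cd8a, above background on 3 of 4 control arrays and on no exposed array, was at least 16.4-fold lower (adjusted p = 0.0054). Its fitted change ran from -5.20 to -1.95 over the alternatives, so this bound does not hold under each of them. The chemokine receptor gene ccr9b (-3.32 ± 0.36), the class II histocompatibility gene mhc2dgb (-3.32 ± 0.75) and the galectin gene lgals9l4 (at least 13.1-fold lower, adjusted p = 0.00159) fell. The fitted change of lgals9l4 ran from -4.76 to -1.34 over the alternatives, so its bound does not hold under each of them either. In lgals9l4 control replicate 2 stood above the other controls, and in mhc2dgb 58.2 mg/L replicate 3 stood below the other exposed arrays. The mhc2dgb call was lost without control replicate 1 (adjusted p = 0.0506) and in the fit of only the groups compared (adjusted p = 0.0719). The nuclear receptor gene nr0b2a (-4.18 ± 0.39, adjusted p = 5.0e-05), the chitinase gene chia.3 (-3.89 ± 0.44), the green opsin opn1mw1 (-3.55 ± 0.58), mfap4.4 (-3.53 ± 0.49), the alcohol dehydrogenase gene adh8a (-3.46 ± 0.44) and the transglutaminase gene tgm2a (-3.35 ± 0.43) fell as well.

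Members of the stress lists rose at 58.2 mg/L. Proteasome genes rose in 24 of 46 members, 38 adjusted over the list alone, with psmb3 (1.68 ± 0.28), psmd7 (1.54 ± 0.25), psmd4b (1.5 ± 0.24) and psmc3 (1.44 ± 0.24) as examples. Their median was 1.11 (adjusted p = 6.2e-25, and adjusted p = 0.105 with an estimated correlation), with 1.89, 0.50 and 1.42 within slides. By fry the proteasome list had adjusted p = 0.000774. Of 38 oxidative stress genes 16 rose, 18 adjusted over the list alone, including me1 (2.26 ± 0.35), pgd (1.98 ± 0.26), gsr (1.89 ± 0.28) and blvrb (1.56 ± 0.21). That list had a median of 0.62 (adjusted p = 5.2e-08, and adjusted p = 0.111 with an estimated correlation), and 0.94 after quantile normalization. By fry the oxidative stress list had adjusted p = 0.00108. Heat shock genes rose in 10 of 32 members, 15 adjusted over the list alone, such as hsp90aa1.1 (3.00 ± 0.33) and hspb8 (2.24 ± 0.33), with a median of 0.43 (adjusted p = 8.3e-10, and adjusted p = 0.0096 with an estimated correlation). Genes of the endoplasmic reticulum and integrated stress list rose in 6 of 49, 8 adjusted over the list alone. They included atf3 (2.26 ± 0.43), mthfd2 (1.34 ± 0.32), calr3b (1.16 ± 0.24) and gpt (1.08 ± 0.25), and the list does not separate the 2 kinds of stress. Their median was 0.23 (adjusted p = 0.000248, and adjusted p = 0.0149 with an estimated correlation).

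Erythroid genes rose in 13 of 32 members at 58.2 mg/L, and 20 were higher and 1 lower adjusted over the list alone. Their median was 1.36 (adjusted p = 4.2e-18, and adjusted p = 0.0096 with an estimated correlation), with 1.71, 1.43 and 1.04 within slides, and the haem synthesis gene hmbsb rose by 2.95 ± 0.27. Lipid synthesis genes had 6 members higher and 2 lower of 39, among them sqlea (2.3 ± 0.43), hmgcra (2.03 ± 0.42) and dgat2 (-2.04 ± 0.38), with adjusted p = 0.000436 (adjusted p = 0.459 with an estimated correlation). The aryl hydrocarbon receptor targets cyp1a (2.77 ± 0.36), cyp1c2 (1.62 ± 0.35), cyp1c1 (1.37 ± 0.33) and gstp1.2 (0.91 ± 0.26) rose, 4 of 18 measured, with a median of 0.57 (adjusted p = 0.000956, and adjusted p = 0.459 with an estimated correlation) and 1.08, 0.52 and 0.19 within slides. Xenobiotic metabolism genes rose in 3 of 50, cyp2k6 (2.47 ± 0.44), cbr1l (1.25 ± 0.24) and ugt5a1 (1.90 ± 0.47), with an adjusted p of 0.0231 that became 0.0556 after quantile normalization and adjusted p = 0.708 with an estimated correlation. Inflammation genes had a median of 0.58 (adjusted p = 0.000222, and adjusted p = 0.482 with an estimated correlation), but 1.03, 0.23 and 0.24 within slides, as 58.2 mg/L replicate 1 had 1.15 and the other exposed arrays 0.20 to 0.41, with saa (2.96 ± 0.73) and the collagenase gene mmp13a (2.78 ± 0.64) higher and nos2a lower among 45.

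Some markers of several tissues were lower at 58.2 mg/L. Epidermal genes fell in 11 of 46 members and rose in 1, with 20 lower adjusted over the list alone, such as the claudin gene cldna (-2.51 ± 0.42) and the keratin gene cyt1 (-1.97 ± 0.41), while krt18a.1 rose by 1.2 ± 0.27. The median was -0.93 (adjusted p = 2.9e-07, and adjusted p = 0.482 with an estimated correlation), with -0.60, -0.57 and -1.5 within slides and -0.56 after normexp and quantile normalization. By fry the epidermal list had adjusted p = 0.0477. Cartilage and bone matrix genes fell in 11 of 52, 14 adjusted over the list alone, including the collagen genes col1a1a (-2.21 ± 0.46) and col2a1a (-1.86 ± 0.41), lum (-1.82 ± 0.39) and ucmaa (-1.76 ± 0.35). Their median was -0.75 (adjusted p = 1.0e-05, and adjusted p = 0.482 with an estimated correlation), with -0.42, -0.41 and -1.34 within slides. Of 44 intestinal genes 7 fell, 13 adjusted over the list alone, and 2 rose, with chia.2 at -1.56 ± 0.30 and chia.6 at 1.56 ± 0.38 (list adjusted p = 0.000789, and adjusted p = 0.611 with an estimated correlation). Photoreceptor genes fell in 3 of 66, opn1mw1, grk7a (-1.56 ± 0.26) and lrata (-1.5 ± 0.39), with an adjusted p of 0.0118 that became 0.0639 after quantile normalization (adjusted p = 0.711 with an estimated correlation). Lens genes had a median of -0.62 (adjusted p = 3.0e-07, and adjusted p = 0.482 with an estimated correlation), with cryaba (-1.64 ± 0.45) alone past the threshold among 69, a call lost in 13 of 31 alternatives. Adjusted over the list alone, 0 lens genes passed. The lens median was -0.35 after loess, -0.26 after normexp with quantile normalization and -0.22 after quantile normalization alone. Neural genes had -0.23 (adjusted p = 0.0212) with vamp1a (-1.04 ± 0.26) past the threshold, exocrine pancreas genes -0.67 (adjusted p = 0.0126), and cell cycle genes -0.68 (adjusted p = 0.00204), each with adjusted p = 0.708 with an estimated correlation. Exocrine pancreas genes had -0.41 after loess, -0.32 after normexp with quantile normalization and -0.34 after quantile normalization alone. With slide as a fixed block that list no longer passed in camera (adjusted p = 0.056). Neural genes had -0.15 after normexp with quantile normalization, and 0 of them passed adjusted over the list alone. The cell cycle median was -2.51, -0.29 and 0.45 within slides. Ribosomal protein genes (-0.59, adjusted p = 8.3e-10, and adjusted p = 0.575 with an estimated correlation) turned to a median of 0.04 after normexp and quantile normalization. Skeletal muscle genes (-0.57, adjusted p = 0.000482, and adjusted p = 0.678 with an estimated correlation) went to -0.05, no longer past the threshold there. In that list desma (0.96 ± 0.23) rose and mylz3 (-0.91 ± 0.25) fell, calls lost in 7 and 23 of the 31 alternatives, where mylz3 ran from -1.14 to -0.34 with an adjusted p of up to 0.307. Adjusted over the list alone, 1 muscle gene was higher and 0 were lower.

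The remaining lists were not shifted at 58.2 mg/L. The glutathione transferase and peroxidase list had 4 members higher and 2 lower of 31. Higher were mgst3b (2.22 ± 0.38), the glutathione synthetase gene gss (1.51 ± 0.26) and gsto1 (1.32 ± 0.25) beside gsta.2. Of 42 DNA damage genes 4 rose, gadd45aa (1.75 ± 0.29), gadd45bb (1.43 ± 0.35), casp3b (0.99 ± 0.28) and baxa (0.86 ± 0.20), with a list adjusted p of 0.113. Liver genes had 6 higher and 4 lower of 50, and the secreted or lipid-binding products ahsg2 (-2.44 ± 0.46) and fabp10a (-2.56 ± 0.51) fell while cyp8b1.1 (2.06 ± 0.35) and tdo2b (1.31 ± 0.27) rose. Fatty acid oxidation genes had 1 higher and 2 lower of 43, cpt1aa (1.03 ± 0.26), fabp1a (-1.77 ± 0.39) and ucp1 (-0.88 ± 0.22). Gluconeogenesis and glucocorticoid genes had 1 of each among 30, star (2.31 ± 0.42) and fbp1b (-1.70 ± 0.31). Arginine, creatine and nitric oxide genes had 2 higher and 3 lower of 31, with oat (1.56 ± 0.36), gch1 (1.07 ± 0.29) and gamt (-1.14 ± 0.31). Single genes rose among the clock genes (nfil3, 1.68 ± 0.31) and metal genes (slc40a1, 2.32 ± 0.36), and atf3 was the one immediate-early gene. None passed among 30 hypoxia, 78 oxidative phosphorylation, 42 neurotransmitter signalling and 15 estrogen-responsive genes, whose list adjusted p were 0.0859, 0.521, 0.893 and 0.521.

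In all 697 genes rose and 500 fell at 58.2 mg/L, with 4543 at an unadjusted p under 0.05. After normexp and quantile normalization 834 rose and 326 fell. The count of 1197 became 760 without control replicate 3, 636 without 58.2 mg/L replicate 1 and 1851 without the 2 arrays with variable spots, and 893 with slide as a block. On the 3 slides with both groups, 1185 of the 1189 called genes with a value on each had 1 sign throughout, again among genes chosen on the same arrays. The 12 largest rises passed under each alternative run, and so did 11 of the 12 largest falls, the exception being mhc2dgb. With slide as a fixed block 11 of the 87 genes named no longer passed, namely gstp1.2, gpt, mthfd2, baxa, casp3b, cpt1aa, gch1, gamt, desma, mylz3 and lrata. Besides mylz3, calls of named genes lost in most alternatives were those of casp3b (21), gstp1.2 (20), gamt (18) and gch1 (16) of up to 31.

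**Figure D3:**
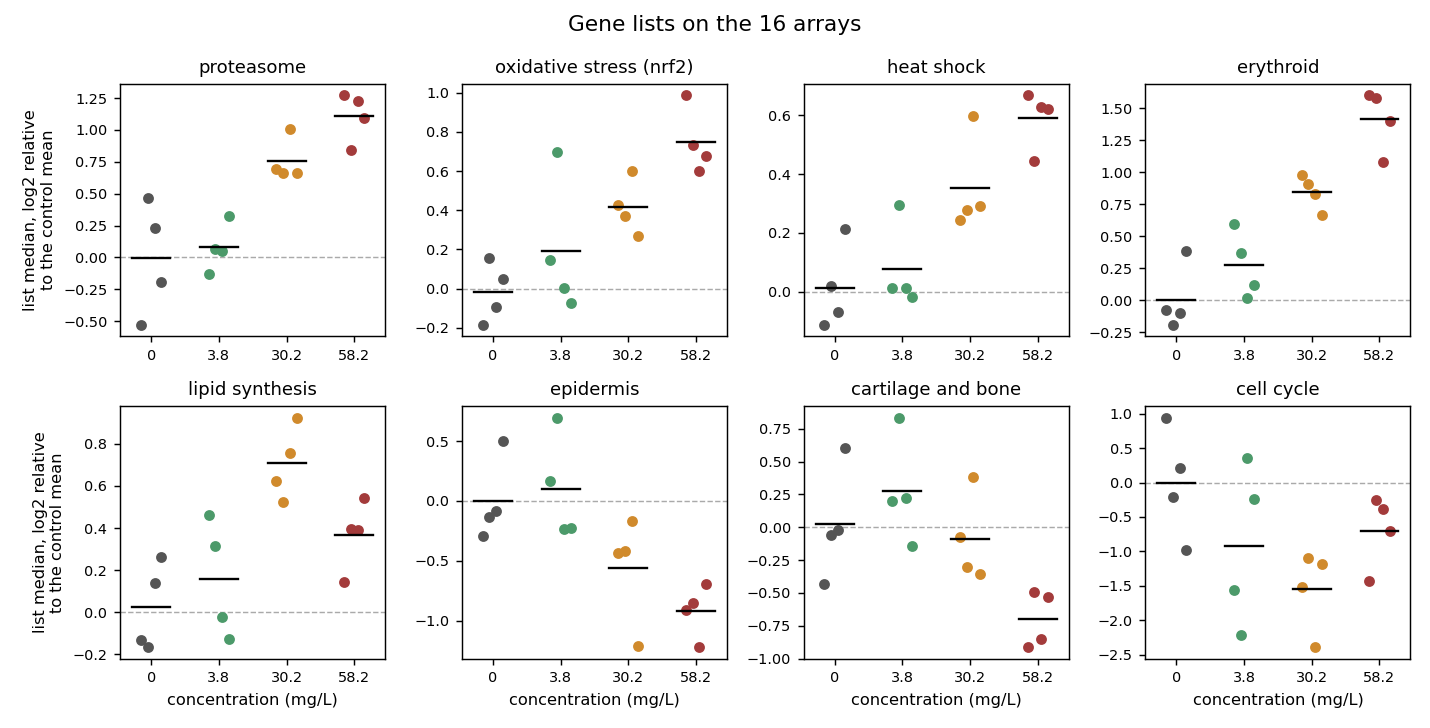
Median of each of 8 gene lists on each of the 16 arrays (dots), in log2 units relative to each gene's control mean, by concentration in mg/L, with black lines for group means and a dashed line at 0. Erythroid arrays at 58.2 mg/L lie between 1.08 and 1.6, above the control arrays at -0.19 to 0.39, while cell cycle medians overlap, from -0.98 to 0.94 in the control and -1.44 to -0.26 at 58.2 mg/L.

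The highest and lowest concentrations were compared directly to ask whether the response depended on dose. Against 3.8 mg/L, the 58.2 mg/L group had higher ptgr1.2 (6.61 ± 0.63), hspa1b (5.63 ± 0.62), hbba2 (5.24 ± 0.84), gsta.2 (5.07 ± 0.68) and hbaa2 (4.80 ± 0.74). At 3.8 mg/L hspa1b was above background on 2 of 4 arrays and ptgr1.2 on 3, and at 58.2 mg/L nos2a was on 1, so the sizes of these 3 differences are uncertain. The 58.2 mg/L group had lower krt1-19e (-6.82 ± 0.47, adjusted p = 3.4e-06), nos2a (-5.97 ± 0.75), opn1mw1 (-4.33 ± 0.58), mfap4.4 (-4.26 ± 0.49) and chia.3 (-4.25 ± 0.44). The gene cd8a was also lower (adjusted p = 0.00254) and was not well above background on any 58.2 mg/L array. The hmox1a difference of 2.27 ± 0.70 had an adjusted p of 0.0791. Erythroid genes (13 of 32 higher, median 1.34, adjusted p = 0.00969 with an estimated correlation) and heat shock genes (10 of 32, 0.71, adjusted p = 0.0047 with an estimated correlation) were higher. So were endoplasmic reticulum and integrated stress genes (8 of 49, 0.40, adjusted p = 0.000694 with an estimated correlation). Proteasome genes were higher in 21 of 46 members (median 1.01, adjusted p = 0.0773 with an estimated correlation), and immediate-early genes in 7 of 36 (median 0.79, adjusted p = 0.183 with an estimated correlation). Oxidative stress genes were higher in 10 of 38 (median 0.48, adjusted p = 1.5e-06 in camera, and adjusted p = 0.183 with an estimated correlation). Lower members were 16 of 52 in cartilage and bone (adjusted p = 0.298 with an estimated correlation), 14 of 46 in epidermis (adjusted p = 0.304 with an estimated correlation) and 9 of 66 among photoreceptor genes (adjusted p = 0.353 with an estimated correlation). In all 454 genes were higher and 570 lower, against 550 and 399 after normexp and quantile normalization, and 4114 had an unadjusted p under 0.05. The count of 1024 became 530 without 3.8 mg/L replicate 1, 580 without 3.8 mg/L replicate 2, 501 without 58.2 mg/L replicate 1 and 581 without 58.2 mg/L replicate 4.

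Between 58.2 and 30.2 mg/L, 7 genes were higher and 24 lower, and of these 5 and 9 had a current symbol. These 14 genes were chosen after their values were seen. The haem synthesis genes hmbsb (2.01 ± 0.27, adjusted p = 0.00964) and urod (1.36 ± 0.18), the glutathione transferase gene gstp1.1 (2.82 ± 0.48), arf4b (2.78 ± 0.52) and ponzr3 (2.28 ± 0.42) were higher at 58.2 mg/L. Lower were krt1-19e (-3.62 ± 0.47, adjusted p = 0.00964), opn1mw1 (-3.74 ± 0.58), chia.3 (-2.68 ± 0.44), nitr2b (-2.63 ± 0.47), ccr9b (-2.22 ± 0.36), pth2 (-1.93 ± 0.34), rps27.2 (-1.45 ± 0.20) and aacs (-1.09 ± 0.19). Above background were nitr2b on 2 and pth2 on 3 of the 58.2 mg/L arrays and gstp1.1 on 3 of the 30.2 mg/L arrays. The recombinase gene rag1, also lower (adjusted p = 0.0347), was not well above background on any 58.2 mg/L array. Differences in ptgr1.2 (3.19, adjusted p = 0.0621), alas2 (1.63, adjusted p = 0.0823), hmox1a (0.81, adjusted p = 0.619) and cyp51 (-1.51, adjusted p = 0.364) did not pass. Endoplasmic reticulum and integrated stress genes had a median difference of 0.29 (adjusted p = 0.00172 with an estimated correlation), the one list past the threshold by that test. Erythroid genes had 0.46 (adjusted p = 3.2e-09, and adjusted p = 0.0909 with an estimated correlation) and lipid synthesis genes -0.47 (adjusted p = 0.00842, and adjusted p = 0.39 with an estimated correlation). Cell cycle genes had 0.93 (adjusted p = 1.3e-12), photoreceptor genes -0.69 (adjusted p = 6.6e-12), lens genes -0.74 (adjusted p = 2.1e-11) and neural genes -0.62 (adjusted p = 2.7e-10), each with adjusted p = 0.31 with an estimated correlation, and exocrine pancreas genes -0.92 (adjusted p = 1.4e-06, and adjusted p = 0.39 with an estimated correlation). Over all genes the median difference was -0.12, and -0.02 with median centring, where 8 genes were higher and 15 lower, and normexp with quantile normalization gave 7 and 9. In limma the count of 31 (2702 at an unadjusted p under 0.05) became 9 without control replicate 3, 14 and 11 without 3.8 mg/L replicates 1 and 3, 0, 11, 6 and 8 without 30.2 mg/L replicates 1 to 4, and 13, 18 and 5 without 58.2 mg/L replicates 1, 2 and 4.

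Responses at 30.2 and 58.2 mg/L were set side by side over all genes. Of the 392 genes called at 30.2 mg/L, 255 were called at 58.2 mg/L in the same direction, 202 higher and 53 lower, and 0 in opposite directions. Unchanged groups simulated against the same controls had a median of 0 calls in each comparison. They had no calls to share, so they set no reference for this overlap. Independent lists of these sizes would share 9.61 higher and 2.00 lower. With the controls split so that each comparison had its own pair, shared calls were 8 to 92 higher and 1 to 11 lower. The changes correlated across genes with r = 0.692, below the 95th percentile of 0.758 in simulated unchanged groups (median 0.503), and with 0.238 to 0.544 when controls were split. Their covariance was 0.355 against a simulated median of 0.0981 and 95th percentile of 0.191, a difference of 0.257 from the median, and 0.163 to 0.3 with split controls. For 3.8 and 30.2 mg/L the correlation was 0.731 (simulated median 0.581, 95th percentile 0.792) and the covariance 0.272 (simulated 0.113 and 0.264). With split controls these were 0.224 to 0.482 and 0.105 to 0.214. For 3.8 and 58.2 mg/L the correlation was 0.399 (simulated 0.513 and 0.768) and the covariance 0.144 (simulated 0.101 and 0.239), and with split controls -0.0416 to 0.206 and -0.0226 to 0.0885. By the moderated F test of limma 988 genes differed between any groups, 4428 at an unadjusted p under 0.05, and the count became 646 without control replicate 3, 534 without 58.2 mg/L replicate 1 and 573 without 58.2 mg/L replicate 4.

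The array's design places the probes of 10 of the genes named above as follows, on Zv9, without saying whether a position is coding or untranslated. The probe of hmox1a spans chromosome 3, 27021597 to 27023156, that of hsp70.3 chromosome 3, 26908284 to 26908343, and that of hbba2 chromosome 3, 55943243 to 55943302. Probes of krt1-19e and cyp51 lie on chromosome 19, at 5963639 to 5963698 and 577387 to 577446. The probe of nr0b2a lies on chromosome 16, 58403785 to 58403844, that of ptgr1.2 spans chromosome 7, 25539537 to 25540345, and that of cyp1a lies on chromosome 18, 4985480 to 4985539. Those of alas2 and opn1lw1 lie on chromosome 8, 21906939 to 21906998, and chromosome 11, 26413429 to 26413488.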

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

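The counts over other splits of the arrays were planned, and the tests of the erythroid, epidermal and cell cycle patterns were chosen after those results had been seen. Values were marked here when the array farthest from the rest of its group of 4 lay at a gap, as a share of the group's range, above Dixon's 95% critical value for 4 samples. Chance marks about 1 in 20 groups. Of 16 groups of array quality values 4 were marked, of 128 groups of list medians 6, and of 102 groups of gene values 5. Control replicate 2 accounted for 5 of the 15, 30.2 mg/L replicate 3 for 4 and 3.8 mg/L replicate 2 for 2.

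Spots left out as irregular numbered 195 on control replicate 2 against 25 to 51 on the other controls (ratio 0.847), and 408 on 30.2 mg/L replicate 3 against 21 to 44 (ratio 0.941). Replicate spots varied by 39.2% on control replicate 2 against 14.0% to 15.1% (ratio 0.956), and by 49.4% on 3.8 mg/L replicate 2 against 14.0% to 17.9% (ratio 0.890). Heat shock genes had a median of 0.29 on 3.8 mg/L replicate 2 against -0.02 to 0.01 on the other arrays of the group (ratio 0.901). On 30.2 mg/L replicate 3 the medians of heat shock genes (0.60 against 0.24 to 0.29, ratio 0.867), hypoxia genes (0.66 against -0.02 to 0.10, ratio 0.833) and proteasome genes (1.01 against 0.66 to 0.69, ratio 0.916) were above the rest. Aryl hydrocarbon receptor targets had a median of -0.50 on 30.2 mg/L replicate 4 against 0.49 to 0.55 (ratio 0.945). Oxidative phosphorylation genes had 0.40 on control replicate 4 against -0.12 to -0.11 (ratio 0.979). Control replicate 2 stood apart in vipr1b (-4.22 against -5.70 to -5.47, ratio 0.841), hist1h2a3 (4.53 against 5.56 to 5.77, ratio 0.835) and lgals9l4 (-1.78 against -3.60 to -3.32, ratio 0.846). At 58.2 mg/L replicate 4 was above the rest in ptgr1.2 (2.02 against 0.84 to 0.87, ratio 0.977), and replicate 3 was below the rest in mhc2dgb (-4.79 against -1.52 to -1.18, ratio 0.904).

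Other groupings of the arrays were counted beside each number of changed genes. For 30.2 mg/L against control 1 of the 35 splits gave as many genes as the real one, itself, with 392 genes and at most 1 in another split. For 58.2 mg/L against control this was 1 of 35, with 1197 genes and at most 180. For 58.2 against 3.8 mg/L it was 1 of 35 (1024 genes, at most 2), and for 58.2 against 30.2 mg/L 1 of 35 (31 genes, at most 1). A share of 1 in 35 is the smallest that these splits can give, and it was not corrected for the number of comparisons. Chance assignment is thus argued against in these 4 comparisons, each taken alone, but not excluded. For 3.8 mg/L against control the real count was 0, which each of the 35 splits (35 of 35) meets by construction, so these splits decide nothing about chance there. The highest of them, 1015 genes, set control replicates 1 and 3 with 3.8 mg/L replicates 3 and 4 against the rest, which points to a structure of these samples that follows no slide. On the first principal component these arrays had scores from -100 to -33.2, and the rest from -29.6 to 114.3. Their cell cycle medians ran from -0.235 to 0.941, and those of the rest from -2.217 to -0.203. For the F test 2 of 100 splits gave as many genes as the real 988, the real one included, a share under 0.05. The other one reached 1124, so chance is not excluded there, and this again points to structure among the samples beyond the groups.

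The erythroid genes were higher at 58.2 mg/L, by a list median of 1.36. A difference between slides as the whole cause is argued against by the lowest within-slide difference of 1.04, and a brightness or GC trend by a median of 1.33 after loess correction. A larger share of red blood cell RNA was tested first by setting 6 embryonic globin genes against the 26 other members. The embryonic globins lay 1.58 ± 1.2 (SE) above the others, inside 2 standard errors, as predicted for such a share. Only a value more than 2 standard errors below the others would have counted against it. With so large a standard error the test decides nothing about the share. A second test, added after that result, found 65.6% of members more than 2 standard errors from the list's median, which argues against an equal rise of all members, but expression of some members in other tissues could also spread them, so that a changed share of red cells, or more transcription within them, stays open beside exposure itself.

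The epidermal genes had a list median of -0.93 at 58.2 mg/L (adjusted p = 2.9e-07, but adjusted p = 0.482 with an estimated correlation), with 11 of 46 members lower and 1 higher in limma. The within-slide difference nearest to 0 was -0.57, and the median after loess correction was -0.70, which argue against a slide difference or a brightness or GC trend as the whole cause. Of the 46 members 28.3% lay more than 2 standard errors from the list's median, which argues against an equal fall of all members, as a smaller share of skin RNA alone would give. Members expressed outside the skin could blur such a fall, so a smaller share of skin in the sampled fish stays open, together with lower transcription in exposed skin. Neither was tested by a measurement of tissue.

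The cell cycle genes varied between arrays of the same group. Over the 11 arrays whose replicate spots varied by under 20% the SD of the list's deviations from the group means was 0.71, against 0.73 over all 16, which argues against spot noise. Pairs of arrays on 1 slide differed in mean square 1.6 times as much as pairs on different slides (ratio 1.603), which argues against a slide difference. Differences in growth or developmental state between beakers may be a cause, but the labels give no measure of either, and no biological explanation was tested.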

How the results depend on the processing

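The fit without the 2 arrays with variable spots and the loess correction were chosen after seeing the data, and all other alternatives were planned. Where a value differed from that reported, the cause was not tested. Leaving out single arrays gave 0 to 1 genes at 3.8 mg/L, 62 to 793 at 30.2 mg/L, 636 to 1499 at 58.2 mg/L, 501 to 1209 for 58.2 against 3.8 mg/L, 0 to 39 for 58.2 against 30.2 mg/L and 534 to 1171 by the F test, and 5 to 14, 10 to 14 and 16 to 20 shifted lists at the 3 concentrations. Slide as a fixed block gave 114 genes at 30.2 mg/L (98 higher, 16 lower, 110 of them among the 392), 11 for 58.2 against 30.2 mg/L, 633 by the F test and 14 lists at 3.8 mg/L, and at 58.2 mg/L 860 of its 893 genes were among the 1197. As a random block slide had a consensus correlation of -0.05. A fit of only the groups compared gave 83 genes at 30.2 mg/L, 660 at 58.2 mg/L and 0 for 58.2 against 30.2 mg/L in limma. Array weights, whose estimation did not converge, gave 59, 3537, 3766, 3888 and 1418 genes in the 5 comparisons and 4353 by the F test. Testing each probe gave 839 at 30.2 mg/L, 2182 at 58.2 mg/L, 1655 for 58.2 against 3.8 mg/L and 1747 by the F test. No filter gave 257 genes at 30.2 mg/L and 15 lists at 3.8 mg/L, and the mean of a gene's probes gave 12 lists there. For 58.2 against 30.2 mg/L normexp gave 16 genes and loess 18. Without the 2 arrays with variable spots 2, 1147 and 1851 genes changed at the 3 concentrations, and 375 of the 392 and 1101 of the 1197 were among them. An estimated correlation gave 0, 0 and 3 lists in order of concentration, and fry 0, 5 and 6. The 5 lists by fry at 30.2 mg/L were erythroid, heat shock, lipid synthesis, proteasome and oxidative stress genes. At 58.2 mg/L lipid synthesis genes no longer passed by fry (adjusted p = 0.0591), while endoplasmic reticulum stress and epidermal genes did.

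With the replicate number as a block, counts were 165 at 30.2 mg/L, 1021 at 58.2 mg/L, 827 for 58.2 against 3.8 mg/L, 8 for 58.2 against 30.2 mg/L and 673 by the F test. The numbers were not shown to pair the arrays. The 24 pairs with the same number had deviations correlated by a median of -0.044 (-0.437 to 0.274), 7 of them over 0.1, and 1 of 16 arrays correlated best with its own number.

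Of 1695 values of genes called at 30.2 mg/L under an alternative, 1331 stayed past the threshold, 364 did not and 0 reversed. At 58.2 mg/L these were 2476, 209 and 0 of 2685. Named genes not called whose sign turned were rpl31 at 30.2 mg/L (0.026 after normexp), rps8a at 3.8 mg/L (0.19 with the mean of probes) and cryabb at 3.8 mg/L (-0.02 without the 2 arrays with variable spots). The signal over background limits genes near it, such as ptgr1.2 in the control, to bounds.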

Other observations

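The test of T cell genes was written before the values of its members were looked at, but it was prompted by cd8a and ccr9b among the largest falls at 58.2 mg/L. T cells are the immune cells that mature in the thymus. Of 39 listed T cell genes 32 were measured, 1 of them also in another list, and several, such as runx1, gata3 and coro1a, are expressed in other cells as well. Without cd8a and ccr9b, 11 of the remaining 30 fell at 58.2 mg/L, 0 rose, and 18 were lower adjusted over the list alone. The kinase genes lck (-2.21 ± 0.32, adjusted p = 0.00116), zap70 (-2.22 ± 0.32, adjusted p = 0.00125) and itk (-1.65 ± 0.27, adjusted p = 0.00266), the co-receptor gene cd4-1 (-2.1 ± 0.31) and the homing receptor gene ccr7 (-2.96 ± 0.46) fell. So did cd8b (-2.90 ± 0.62, above background on 3 arrays of each group), lat (-1.75 ± 0.40), cd247 (-1.30 ± 0.35), foxp3a (-1.06 ± 0.23) and cd4-2.1 (-1.54 ± 0.40, above background on 1 exposed array). The recombinase gene rag1, which assembles antigen receptor genes in developing lymphocytes, fell to below background on the 4 exposed arrays (adjusted p = 0.00173). Members that did not pass included coro1a (-0.58, adjusted p = 0.319, normalized control signal 3.44) and runx3 (-1.03, adjusted p = 0.213, normalized control signal 1.88).

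The 30 genes had a median change of -1.06 at 58.2 mg/L, -1.39 to -0.66 within slides and -1.06 after loess correction, and 27 were negative. In camera the list had p = 2.9e-12 with the preset correlation and p = 0.00913 with an estimated correlation. At 30.2 mg/L the median was -0.38 with 0 genes past the threshold in limma, and at 3.8 mg/L it was 0.25. The values are consistent with a smaller share of T cell or thymus RNA in larvae that survived 58.2 mg/L, as a hypothesis found and tested on the same arrays. Lower transcription within T cells may give the same values, and the arrays do not separate the 2.

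Embryonic globin genes had a median change of 2.95 at 58.2 mg/L, with values from -1.0 in hbbe2 to 3.47 in hbae1.1 (adjusted p = 0.0672), and none of the 6 passed in limma. The first principal component held 28.9% of the variance and the second 18.1%. Scores on the second ran from 1.6 to 62.2 over the control and 3.8 mg/L arrays and from -77.2 to -9.4 over the 30.2 and 58.2 mg/L arrays. On the first, arrays of 1 group spread from -100 to 13.5 in the control and from -56.2 to 114.3 at 3.8 mg/L.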
